A study of Rattus norvegicus with 4 samples.

How the data were processed

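Lung mRNA was measured in 4 libraries, 2 from bleomycin-treated and 2 from saline-treated rats, each from 1 rat per the labels. Per the labels' protocols, messenger RNA was enriched with oligo(dT) beads, fragmented and reverse transcribed with random primers; no strand-marking step is described, so reads of overlapping antisense genes were not told apart. Per the submitters' processing notes, CASAVA 1.8, fastp 0.18.0, HISAT2, StringTie 1.3.1 and DESeq2 were used with the rat build Rnor_6.0; their settings are not given in the sources used here. Each library's file gave whole-number counts per gene, as deposited by the authors without normalization, and length-scaled FPKM values that the authors deposited beside them. The ratio of count to FPKM between libraries followed the ratio of total counts, with a median of 1.2552 for control replicate 2 over control replicate 1, equal to the ratio of their totals, so the FPKM were scaled to each library's summed gene counts. Enriching for poly(A) RNA leaves out transcripts without a tail, and random priming after fragmentation makes counts grow with transcript length, so CPM values compare a gene between libraries better than genes with each other.

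The files list 22050 genes by Ensembl identifier and symbol. For 25 genes a spreadsheet had turned the symbol into a date, and these were kept under their identifier; 178 genes shared a symbol with another gene and were kept apart by identifier. Of the symbols, 16648 matched the RefSeq gene table of the GRCr8 assembly, which differs from the build of the files, so none of its coordinates were used. No column of other samples was present.

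Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (a minimum count of 10, which is 0.242 CPM at the median depth, in at least 2 libraries, and 15 counts in all), scaled with the trimmed mean of M values (TMM), and tested with the quasi-likelihood F test with robust dispersion estimates, with group as the only term. Benjamini-Hochberg adjusted p under 0.05 counted as a call. With 2 libraries per group the fit has 2 residual degrees of freedom of its own, to which the shared estimate of spread added a median of 3.30. CPM values use the TMM-scaled library sizes. The scaling left the median log2 change of all tested genes at 0.013. A gene with no control count was given a lower bound against 3 counts summed over both controls, and one with 1 to 3 control counts an exact 95% interval of the ratio; both cover counting error only, and PCR copies are not independent molecules.

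Gene lists, 33 in number, and the rule for the genes named in the text were fixed before the data were examined. The rule took the 6 largest rises and the 6 largest falls among called genes with a mean log2 CPM of at least 1, a gene symbol and groups that do not overlap; from each list the 2 members with the smallest p and, where 3 or more passed, the called member with the highest mean CPM; and a panel of 12 genes. Placeholder names such as locus numbers were not taken as gene symbols. This gave 107 genes. Of the 566 list entries, 20 were not found under their symbol. Lists were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 33 lists, and again with an estimated correlation and with fry. With an estimated correlation camera takes its p from the 2 residual degrees of freedom of the fit, and with a preset one from the number of genes. Counts "adjusted over the list alone" use Benjamini-Hochberg adjustment among a list's tested members. Lists named for a cell type hold genes that other lung cells also express, so they describe transcripts and not cell numbers.

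Replicates were compared before averaging. Counts of the control pair differed by 22.6 times the sampling variance and those of the bleomycin pair by 96.7 times, over genes with at least 20 counts, so no library was a copy of another.

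The test was tried on simulated counts drawn with the means, library sizes and dispersions of the real data for 15709 genes, of which 200 were changed. The changed genes were drawn from those with a mean log2 CPM of at least 1, so weaker genes are not covered. Both groups were given the same dispersion, while the real bleomycin pair varied more than the control pair. In the real data 17.0% of tested genes were called, so the simulated shares do not carry over directly. In the comparison of bleomycin against control the test recovered 82% of genes raised 2-fold, 96% raised 4-fold, 62% lowered 2-fold and 94% lowered 4-fold. Of 191 calls, 24 were unchanged genes, and over 10 further draws the median share of such calls was 12.6% (from 6.4% to 18.4%), above the nominal 5%, so adjusted p-values near the threshold are to be read as optimistic. With no changed gene at all, the draws gave a median of 1.5 calls and at most 9. Camera called 4 of 4 changed lists and 0 of 30 unchanged lists in simulated data where genes vary independently.

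The alternatives were other scaling factors (relative log expression, upper quartile, or library size only), no filter beyond 1 count, a filter of 50 counts in 2 libraries, DESeq2 1.42.0, limma-voom, non-robust dispersions, the earlier edgeR method, the replicate number as a block, each library left out in turn, a 2-fold threshold, and limma on log2(FPKM + 1) and log2(FPKM + 0.1). Counts of called list members without bleomycin replicate 1 and without control replicate 1 were added after the data were seen. Folds without a library are ratios of the remaining libraries' CPM, and bounds keep the same floor.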

Results

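Whole-lung mRNA was profiled in Sprague-Dawley rats (SD rats in the labels) 28 days after a single intratracheal injection of 0.2 mL. Bleomycin, an antitumour antibiotic that breaks DNA and is widely used to induce lung fibrosis in rodents, was injected at 5 mg/kg in the treated rats, and saline in the controls. There were 2 bleomycin libraries and 2 control libraries, each from 1 rat per the labels. Counts summed over genes were 34683699 and 43533928 in control replicates 1 and 2, and 39168063 and 44381111 in bleomycin replicates 1 and 2, so 3 counts corresponded to between 0.0676 and 0.0865 CPM (a gene's counts scaled to the library's total) in a library. The comparison asked which genes differed in abundance between bleomycin-treated and saline-treated lungs at that time. Group values are mean ± SD over n = 2 libraries, and log2 fold changes are bleomycin over control with a standard error (SE). This SE was derived from the test, as the log2 change fitted without shrinkage divided by the square root of the F statistic. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists are from camera. Chromosomal positions are not given here.

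In bleomycin-treated lungs 11 of 20 tested collagens, 13 of 17 recruited macrophage markers, 11 of 15 complement genes and 23 of 28 cell cycle genes rose and none of them fell, while 11 of 14 alveolar type 1 markers and 9 of 18 ciliated cell markers fell and none rose. As lists these passed by camera with a preset correlation. With an estimated correlation, where camera's p rests on only 2 degrees of freedom, none did. Camera adjusted p was then 0.411 for the collagen, macrophage and complement lists and 0.427 for the other 3. None passed by fry. Col1a1, a chain of type I collagen, was 8.69-fold higher, at 3568 ± 2262 CPM against 410.5 ± 29.2 CPM, or 4.79-fold without bleomycin replicate 1. Spp1, which encodes the secreted protein osteopontin, was 40.4-fold higher, at 384 ± 159 CPM against 9.50 ± 1.997 CPM. Scgb1a1, the secretory protein of club cells, was 4.99-fold lower, at 1974 ± 292 CPM against 9843 ± 442 CPM.

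In all, 15709 genes were tested, of which 1455 were higher and 1223 lower in bleomycin-treated lungs at an adjusted p under 0.05 by edgeR's quasi-likelihood test. At least 2-fold changes accounted for 880 of the higher and 622 of the lower genes, and at least 4-fold changes for 356 and 128. Both bleomycin libraries lay on the same side of both control libraries for 68.5% of tested genes and for all 2678 called genes. Chance gives 33.3% for a single gene, but genes vary together, so any split of the libraries can lead by chance. The share is therefore no test of the treatment. The smallest adjusted p by edgeR was 0.00546. Without control replicate 1 the test called 9 higher and 8 lower genes and without control replicate 2 it called 9 and 6; the lone control is then assumed to vary like the bleomycin pair. Without bleomycin replicate 2 it called 2750 and 2612 genes.

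**Figure D1:**
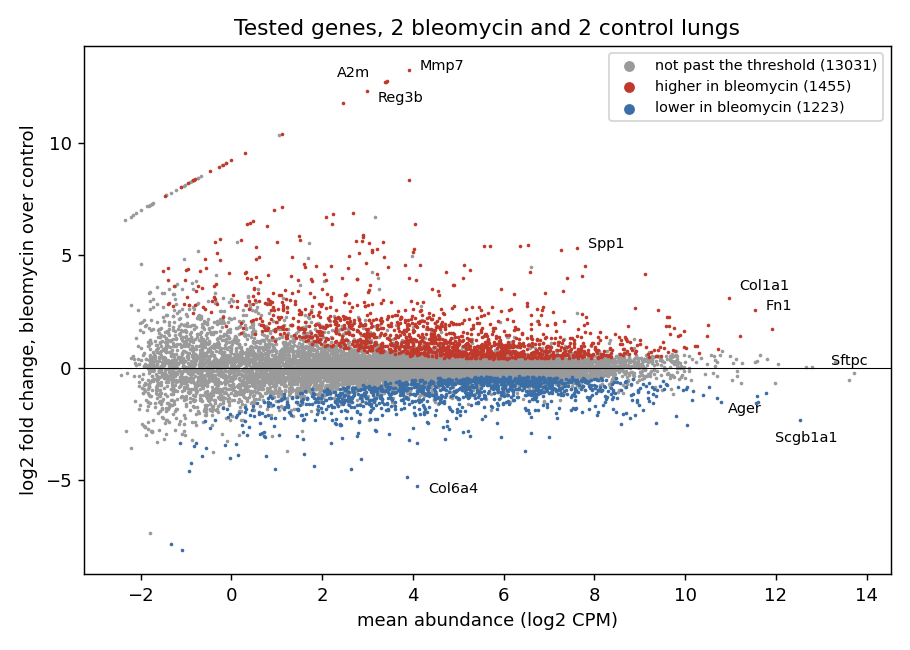
Each point is a tested gene, with mean abundance in log2 CPM on the horizontal axis and the fitted log2 fold change of bleomycin over control on the vertical axis. Red points are the 1455 genes called higher and blue points the 1223 called lower at an adjusted p under 0.05 by edgeR; the rising line of points at the upper left is genes with 0 counts in both controls, whose fitted fold change is no bound.

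The 6 named genes with the largest fitted rise were at or near 0 in the controls. Mmp7 (ENSRNOG00000010507), the metalloproteinase matrilysin, had no count in either control and 39.7 and 20.6 CPM in bleomycin replicates 1 and 2, at least 785-fold higher against a floor of 3 counts over both controls (0.0384 CPM). Against the same floor, A2m (ENSRNOG00000028896), the protease inhibitor alpha-2-macroglobulin, was at least 559-fold higher, with 33.8 and 9.12 CPM in bleomycin replicates 1 and 2, a bound of 237-fold without replicate 1 and 879-fold without replicate 2. Reg3b (ENSRNOG00000006151), a secreted antimicrobial lectin, was at least 410-fold higher, with 7.83 and 23.7 CPM, a bound of 616-fold without bleomycin replicate 1 and 204-fold without replicate 2. Fgf23 (ENSRNOG00000052205), a phosphate-regulating hormone, was at least 285-fold higher, and Calcb (ENSRNOG00000011074), which encodes the beta form of calcitonin gene-related peptide, at least 109-fold higher, or 72.1-fold without bleomycin replicate 1. Trh (ENSRNOG00000011824), the thyrotropin-releasing hormone precursor, had 7 control counts, all in replicate 1, and was 296-fold higher at 30.02 ± 14.61 CPM, or 194-fold without bleomycin replicate 1 and 148-fold without control replicate 2. Reads of A2m and Reg3b could be shared with related family members, which was not tested, and the levels of both genes are uncertain to that extent. Adjusted p of these 6 genes by edgeR lay between 0.00947 for Trh and 0.0285 for A2m. Without control replicate 1 the fitted log2 change of Trh went from 8.33 to 13.31 with an edgeR adjusted p of 0.0612.

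The 6 named genes with the largest fall were each present in both controls. Col6a4 (ENSRNOG00000031782), a type VI collagen chain, was 38.1-fold lower, at 0.873 ± 0.305 CPM against 33.3 ± 13.6 CPM (edgeR adjusted p = 0.00947). Slc5a1 (ENSRNOG00000017775), a sodium-glucose cotransporter, was 29.4-fold lower. Bmp15 (ENSRNOG00000002984), a growth factor best known from the oocyte, fell 22.7-fold from 11.8 ± 1.1 CPM, and the homeobox gene Nkx2-8 (ENSRNOG00000022970) fell 20.5-fold from 6.70 ± 0.31 CPM. Adcy1 (ENSRNOG00000059479), an adenylyl cyclase, was 17.2-fold lower (10.9-fold without bleomycin replicate 1, 41.1-fold without replicate 2) and Sstr1 (ENSRNOG00000048145), a somatostatin receptor, 14.5-fold lower.

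A panel of 12 genes had been named in advance whatever their outcome. Besides Col1a1 (ENSRNOG00000003897) and Spp1 (ENSRNOG00000043451), the collagen gene Col3a1 (ENSRNOG00000003357) rose by 1.71 ± 0.29 on the log2 scale, fibronectin, Fn1 (ENSRNOG00000014288), by 2.56 ± 0.32, the protease inhibitor Timp1 (ENSRNOG00000010208) by 3.43 ± 0.39 (10.8-fold, or 7.08-fold without bleomycin replicate 1) and macrophage elastase, Mmp12 (ENSRNOG00000030187), by 5.41 ± 0.33. Tgfb1 (ENSRNOG00000020652), which encodes transforming growth factor beta 1, rose 1.52-fold, from 97.4 ± 3.9 to 147.6 ± 17.4 CPM (edgeR adjusted p = 0.0338). The cell cycle inhibitor Cdkn1a (ENSRNOG00000000521) rose 2.46-fold with an edgeR adjusted p of 0.0353, which became 0.151 without bleomycin replicate 1 and 0.127 without bleomycin replicate 2. Aqp5 (ENSRNOG00000051970), a water channel of alveolar type 1 cells, fell 2.61-fold. Acta2 (ENSRNOG00000058039), the smooth muscle actin used as a myofibroblast marker, did not pass, with a log2 fold change of 1.09 ± 0.33 and an edgeR adjusted p of 0.0803. Sftpc (ENSRNOG00000011177), the surfactant protein of alveolar type 2 cells, had 6822 and 13620 CPM in bleomycin replicates 1 and 2 against 15430 and 14330 CPM in controls 1 and 2 (edgeR adjusted p = 0.323). Blmh (ENSRNOG00000003563), the hydrolase that inactivates bleomycin, was at 83.0 ± 2.2 CPM against 71.8 ± 1.2 CPM (edgeR adjusted p = 0.176).

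**Figure D2:**
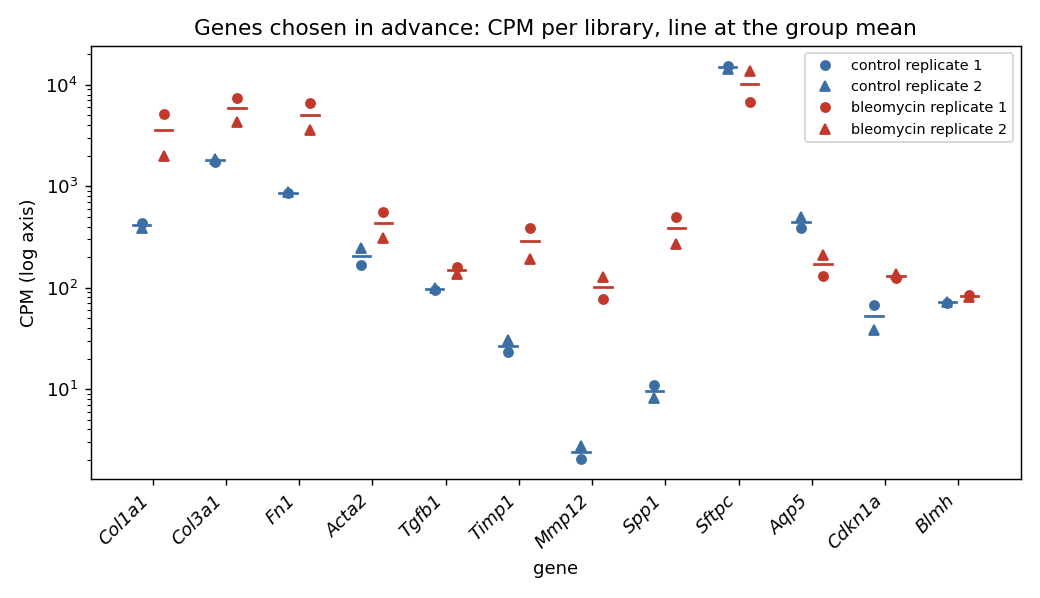
CPM on a log axis for the 12 genes named in advance, with control libraries in blue, bleomycin libraries in red, circles for replicate 1, triangles for replicate 2 and a short line at each group mean. Col1a1 was at 5167 and 1968 CPM in the bleomycin libraries and at 431.1 and 389.8 CPM in the controls.

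The bleomycin libraries differed from each other more than the controls did. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.982 between the controls and 0.974 between the bleomycin libraries. Bleomycin replicate 1 lay farther from the control mean than replicate 2 for 2150 of the 2678 called genes (80.3%), and for the median of 22 of the 24 called gene lists. Heart muscle transcripts were high in control replicate 1. There the heart myosin gene Myh6, chosen after its values were seen, had 77.3 CPM. It had 2.50 CPM in control replicate 2 and 18.6 CPM in each bleomycin library.

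Camera, which sets a list's genes against all other tested genes, called 24 of the 33 gene lists fixed in advance, 16 upward and 8 downward. These calls use a preset inter-gene correlation of 0.01. With an estimated correlation no list passed, 3 lists had an unadjusted p under 0.05, and adjusted p of the 24 lists lay between 0.411 and 0.624. This held also where the estimated correlation lay below the preset, as for the cytokine list (0.00512) and the p53 list (-0.0268). The loss of calls is thus not due to correlated members alone. With an estimated correlation camera takes its p from 2 residual degrees of freedom, so small p-values were hard to reach. Failing that test therefore says little about a list. By fry, which asks whether a list's genes move on balance one way, no list passed either; 14 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0816. Without either control, 4 list members in all were called by edgeR, so the member counts given for each list rest on having both controls. No median of a list changed when genes with 0 control counts were set at their bound.

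Of 20 tested collagens, 11 rose and none fell, 15 rose when p-values were adjusted over the list alone, and the median log2 change was 1.54 (camera adjusted p = 4.06e-10; adjusted p = 0.411 with an estimated correlation). Col16a1 rose 2.88-fold and Col8a2 2.96-fold. Of 20 genes of collagen processing and cross-linking, 8 rose and 1 fell, or 15 and 1 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 1.39e-06; adjusted p = 0.427 with an estimated correlation). The collagen lysyl hydroxylase gene Plod2 rose 5.99-fold, the lysyl oxidase family gene Loxl1 3.95-fold and the collagen chaperone gene Serpinh1 1.72-fold. Pcolce2, which encodes an enhancer of procollagen processing, was the member that fell, by 2.08 on the log2 scale. In this list 15 members rose and 1 fell without bleomycin replicate 2. Of 27 matrix glycoproteins and proteoglycans, 16 rose and 1 fell, or 20 and 1 adjusted over the list alone, with a median of 1.3 (camera adjusted p = 3.53e-13; adjusted p = 0.411 with an estimated correlation). Thbs2, which encodes the matrix glycoprotein thrombospondin 2, rose 42.5-fold, from 3.80 ± 0.73 to 161.1 ± 74.0 CPM, and the member that fell was Fbln2, by 1.38 on the log2 scale. Leaving out bleomycin replicate 2 gave 21 higher and 2 lower members of this list. Pcolce2 and Fbln2 were named after their values were seen.

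Among 17 metalloproteinases and inhibitors, 11 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 change of 1.38 (camera adjusted p = 3.85e-09; adjusted p = 0.411 with an estimated correlation). Adamts4, an aggrecan-cleaving protease gene, rose 21.5-fold (43.1-fold without control replicate 1, 14.3-fold without control replicate 2), while the inhibitor gene Timp3 fell 1.67-fold; without bleomycin replicate 2, 14 members rose and 2 fell. The TGF-beta pathway list went both ways, with 10 of 24 members higher and 4 lower, 13 and 5 adjusted over the list alone, and a median of 0.32. Its camera adjusted p was 0.0177, against 0.411 with an estimated correlation and 0.0995 by camera without control replicate 2. The bone morphogenetic protein antagonist gene Grem1 rose 22.9-fold, while Acvrl1, an endothelial receptor gene of the family, fell from 665.0 ± 61.7 to 333.2 ± 51.9 CPM.

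Of 14 smooth muscle and myofibroblast contractile genes, 3 rose, with the same number adjusted over the list alone, and the median log2 change was 0.71. The camera adjusted p of this list was 0.00481, against an adjusted p of 0.624 with an estimated correlation and 0.0847 by camera without bleomycin replicate 1. Smtn rose by 1.03 ± 0.19 on the log2 scale and the actin-binding protein gene Cald1 by 0.61 ± 0.12. The contractile median was 0.354 without bleomycin replicate 1, and 5 members rose without bleomycin replicate 2. Between the controls, replicate 1 minus replicate 2, the median log2 difference of this list was -0.552. Of 15 alveolar fibroblast and pericyte markers, 4 rose, or 7 with 2 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.157). The growth factor gene Wnt2 rose 2.40-fold and the integrin gene Itga8 1.79-fold. The fibroblast list had 7 members higher and 3 lower without bleomycin replicate 2, and 3 and 1 without bleomycin replicate 1.

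Epithelial lists moved apart. Of 14 alveolar type 1 markers, 11 fell and none rose, with the same counts adjusted over the list alone and a median log2 change of -1.14 (camera adjusted p = 1.62e-08; adjusted p = 0.427 with an estimated correlation). Ager, the receptor gene that marks these cells, fell 2.56-fold, from 2404 ± 196 to 939 ± 248 CPM, Spock2 fell 3.48-fold and the basement membrane collagen gene Col4a3 2.67-fold. Of 11 alveolar type 2 markers none passed, also adjusted over the list alone, and the list median was -0.02 (camera adjusted p = 0.182), or 0.212 without bleomycin replicate 1 and -0.339 without bleomycin replicate 2. Sftpb had a log2 change of -0.69 ± 0.24 (edgeR adjusted p = 0.107) and the transcription factor gene Etv5 of -0.99 ± 0.28 (edgeR adjusted p = 0.066). Without bleomycin replicate 2, 6 type 2 markers fell and the list passed downward (camera adjusted p = 0.000188), and without bleomycin replicate 1, 1 fell.

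Of 14 keratins and genes of injury-associated epithelium, 6 rose, or 9 adjusted over the list alone, with a median log2 change of 1.79 (camera adjusted p = 6.99e-06; adjusted p = 0.427 with an estimated correlation). Sfn rose 23.1-fold, with 39.7 and 14.8 CPM in bleomycin replicates 1 and 2 (12.5-fold without replicate 1), the epidermal growth factor family gene Areg 7.46-fold and the galectin gene Lgals3 2.87-fold. The keratin list's median was 1.03 without bleomycin replicate 1, with 6 members higher, and 11 members rose without bleomycin replicate 2. Of 18 ciliated cell markers, 9 fell and none rose, or 17 adjusted over the list alone, with a median of -0.89 (camera adjusted p = 2.05e-09; adjusted p = 0.427 with an estimated correlation). The axonemal dynein gene Dnai1 fell 2.98-fold, Tppp3 2.56-fold and Ak7 2.03-fold. All 18 fell without bleomycin replicate 2. Of 12 secretory and mucous cell markers, 2 rose and 2 fell, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.94, or 0.0171 downward without bleomycin replicate 1); its median was 0.06 while camera's direction was downward. The iron-chelating lipocalin gene Lcn2 rose 6.38-fold where Scgb1a1 fell, and it was not called without bleomycin replicate 1 (edgeR adjusted p = 0.0583). The secretory list had 1 higher and 3 lower members without bleomycin replicate 1, and 3 and 4 without bleomycin replicate 2.

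Of 19 endothelial markers, 9 fell and 2 rose, or 12 and 2 adjusted over the list alone, with a median log2 change of -0.81 (camera adjusted p = 1.32e-06; adjusted p = 0.427 with an estimated correlation). The angiopoietin receptor gene Tek fell 3.71-fold, the adrenomedullin receptor component gene Ramp2 2.65-fold and Vwf, von Willebrand factor, 2.03-fold, from 1553 ± 111 to 766 ± 57 CPM. The members that rose were Nos3, endothelial nitric oxide synthase, by 0.51 ± 0.12, and Egfl7, a secreted endothelial protein gene, by 0.60 ± 0.12 on the log2 scale, both named after their values were seen. In the endothelial list 14 members fell and 1 rose without bleomycin replicate 2. Of 13 genes of xenobiotic metabolism, 9 fell and 1 rose, with the same counts adjusted over the list alone and a median of -1.40 (camera adjusted p = 6.84e-10; adjusted p = 0.411 with an estimated correlation). The flavin-containing monooxygenase gene Fmo2 fell 4.01-fold, and the carboxylesterase gene Ces1d fell 4.25-fold. None of the xenobiotic genes rose without bleomycin replicate 1.

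Of 17 recruited macrophage markers, 13 rose, or 13 with 1 lower adjusted over the list alone, with a median log2 change of 1.97, and this list had the smallest p of the 33 (camera adjusted p = 2.03e-23; adjusted p = 0.411 with an estimated correlation). The cysteine protease gene Ctsk rose 19.4-fold, the apolipoprotein gene Apoe 6.02-fold, from 193.5 ± 4.0 to 1165 ± 50 CPM, and Gpnmb 3.39-fold; without bleomycin replicate 2, 1 member fell. Of 12 alveolar macrophage markers, 2 rose and 2 fell, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.329). The fatty acid-binding protein gene Fabp5 rose 2.79-fold and the scavenger receptor gene Olr1 2.29-fold, while Cd9 fell 1.49-fold; without bleomycin replicate 1, 1 alveolar macrophage marker fell. Of 10 MHC class II genes, 7 rose, or 8 adjusted over the list alone, with a median of 0.90 (camera adjusted p = 9.09e-07; adjusted p = 0.411 with an estimated correlation). Ciita, the transactivator of these genes, rose 2.04-fold, RT1-DMb 1.90-fold and RT1-Da 1.83-fold; RT1 genes resemble each other, so reads could be split between them.

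Of 15 complement genes, 11 rose, or 14 adjusted over the list alone, with a median log2 change of 1.37 (camera adjusted p = 6.44e-15; adjusted p = 0.411 with an estimated correlation). C6, a component of the membrane attack complex, rose 37.5-fold, from 7.996 ± 0.195 to 300.2 ± 58.1 CPM, and had the smallest adjusted p of any gene by edgeR (0.00546). Cfi, complement factor I, rose 4.17-fold. C4a rose 2.62-fold, but its near-identical copy C4b leaves it uncertain, and it was not called without bleomycin replicate 1 (edgeR adjusted p = 0.211) or replicate 2 (edgeR adjusted p = 0.0857). Of 34 cytokines and chemokines, 11 rose and 1 fell, or 14 and 1 adjusted over the list alone, with a median of 0.93 (camera adjusted p = 9.6e-06; adjusted p = 0.411 with an estimated correlation). The chemokine gene Cxcl6 rose 30.1-fold (62.6-fold without control replicate 1, 19.8-fold without control replicate 2), Ccl21 2.49-fold and Cxcl16 1.94-fold. Ccl5, named after its values were seen, was the member that fell, by 1.75 on the log2 scale. Without bleomycin replicate 2, 16 members of the cytokine list rose and 4 fell, and without bleomycin replicate 1, 13 rose and 2 fell.

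Haemoglobin and erythroid genes, fixed as a check of blood in the samples, were lower, with 5 of 6 lower, also adjusted over the list alone, and a median log2 change of -0.89 (camera adjusted p = 0.00229; adjusted p = 0.427 with an estimated correlation). Hbb fell 1.92-fold, Hba-a1 1.79-fold and Hba-a2 by 0.85 ± 0.18 on the log2 scale, genes whose near-identical copies can share reads. Without bleomycin replicate 1 no member of the blood list was called, although the list still passed (camera adjusted p = 0.0277). Beside this, 7 of 11 natural killer and cytotoxic genes fell, or 8 adjusted over the list alone, with a median of -1.54 (camera adjusted p = 6.02e-05; adjusted p = 0.427 with an estimated correlation). The perforin gene Prf1 fell 3.36-fold (5.59-fold without bleomycin replicate 2), the natural killer receptor gene Ncr1 3.23-fold and the transcription factor gene Tbx21 2.46-fold. Of 14 B cell and plasma cell markers, 5 fell, or 6 with 1 higher adjusted over the list alone, with a median of -0.75 (camera adjusted p = 0.00481; adjusted p = 0.427 with an estimated correlation). Bank1, a B cell adaptor gene, fell 10.4-fold and Cd22 2.24-fold, and without bleomycin replicate 2, 6 members fell and 2 rose, while without bleomycin replicate 1, 5 fell and 1 rose. Of 18 T cell markers, 2 rose and 2 fell, or 2 and 3 adjusted over the list alone, and the list did not pass (median -0.06, camera adjusted p = 0.924). The T cell median was -0.287 without bleomycin replicate 1 and 0.168 without bleomycin replicate 2. Icos, a costimulatory receptor gene, rose 4.27-fold and Cd4, which macrophages also express in rats, 1.61-fold; without bleomycin replicate 1, 1 T cell marker fell.

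Of 16 neutrophil and mast cell markers, 7 rose, or 7 with 1 lower adjusted over the list alone, with a median log2 change of 0.75. The camera adjusted p was 0.0133, against an adjusted p of 0.411 with an estimated correlation and 0.123 by camera without bleomycin replicate 2. All 7 members that rose encode mast cell products or receptors, namely the proteases Cma1, Cpa3, Tpsab1 and Tpsb2, the immunoglobulin E receptor chains Fcer1a and Ms4a2, and Hdc, which makes histamine; the last 4 were named after their values were seen. Cma1 rose 24.3-fold, from 2.75 ± 2.08 to 66.8 ± 10.5 CPM, Tpsab1 21.2-fold and Cpa3 6.06-fold. Reads of Tpsab1 could be shared with the related gene Tpsb2, which was not tested, so the level of Tpsab1 is uncertain to that extent. Without control replicates 1 and 2 in turn the folds were 15.8 and 52.4 for Cma1 and 13.5 and 49.3 for Tpsab1. Without bleomycin replicate 1, 4 members rose, and the edgeR adjusted p was then 0.0642 for Tpsab1 and 0.074 for Cpa3. Leaving out bleomycin replicate 2 instead, 5 members rose and 2 fell, and the edgeR adjusted p of Cpa3 was 0.0591. The list's median was 0.217 without bleomycin replicate 1, 1.34 without control replicate 1 and 1.16 without control replicate 2. Kit, the stem cell factor receptor gene of mast cells and other cells, named after its values were seen, had a log2 change of -1.23 ± 0.48 and did not pass (edgeR adjusted p = 0.135). Of 25 interferon response genes, 6 fell and none rose, or 11 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 5.42e-05; adjusted p = 0.519 with an estimated correlation). Without control replicate 2 the interferon median was -0.273 and the list still passed (camera adjusted p = 0.0168); the controls themselves, replicate 1 minus replicate 2, differed by a median of -0.374 over this list. Bst2 fell 2.04-fold, Gbp5 1.99-fold and Ifi44l 1.83-fold.

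Of 28 cell cycle genes, 23 rose, or all 28 adjusted over the list alone, with a median log2 change of 1.94 (camera adjusted p = 8.28e-18; adjusted p = 0.427 with an estimated correlation). The proliferation marker gene Mki67 rose 4.17-fold, from 22.5 ± 2.1 to 94.0 ± 27.8 CPM, the mitotic checkpoint kinase gene Bub1 3.52-fold and the replication clamp gene Pcna 1.48-fold. Of 18 p53 targets and senescence genes, 8 rose, or 9 adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.00127; adjusted p = 0.411 with an estimated correlation). Cdkn2a, whose products include the cell cycle inhibitor p16, rose 17.5-fold, from 0.262 ± 0.084 to 4.59 ± 0.68 CPM. Counts per gene do not tell its transcripts apart. Ccng1, cyclin G1, rose 1.67-fold. Of 16 antioxidant genes, 5 rose, or 7 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 0.00454; adjusted p = 0.427 with an estimated correlation). The cystine transporter gene Slc7a11 rose 36.9-fold (24.5-fold without bleomycin replicate 1), Sod2, mitochondrial superoxide dismutase, 1.99-fold and the glutathione peroxidase gene Gpx1 1.51-fold. Among the antioxidant genes 9 rose and 3 fell without bleomycin replicate 2.

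The remaining lists checked other tissue, handling and sex, or covered lipid synthesis. Of 17 genes of cholesterol and fatty acid synthesis, 1 rose, none did adjusted over the list alone, and the list did not pass (median 0.01, camera adjusted p = 0.94). The sterol reductase gene Dhcr7 was that gene, at 0.88 ± 0.22 on the log2 scale with an edgeR adjusted p of 0.0497, or 0.103 without bleomycin replicate 1, and Idi1 did not pass at 0.70 ± 0.17. Without bleomycin replicate 2, 1 gene of that list rose and 5 fell, and without bleomycin replicate 1, 2 rose. Of 7 mesothelium and fat genes, 2 rose, with the same number adjusted over the list alone, and the median was 1.06. The camera adjusted p was 0.0402, against 0.427 as an adjusted p with an estimated correlation, and by camera 0.273 without control replicate 2, 0.336 without bleomycin replicate 1 and 0.0677 without bleomycin replicate 2. The mesothelial genes Wt1 and Lrrn4 rose 5.05-fold and 2.09-fold, with 7.58-fold for Wt1 without control replicate 2 and 2.83-fold without bleomycin replicate 1, but Wt1 was not called without bleomycin replicate 1 (log2 change 1.46, edgeR adjusted p = 0.0778), which left 1 member. The median of the mesothelium and fat list was 1.85 without control replicate 1 and 0.353 without bleomycin replicate 1. Of 13 heart muscle genes none passed, also adjusted over the list alone (median -1.09, camera adjusted p = 0.921). Without control replicate 1, the library with high heart transcripts, the heart list's median was 2.14 and it passed upward (camera adjusted p = 6.13e-08), and without control replicate 2 it passed downward (camera adjusted p = 3.89e-11), while 1 heart gene rose without bleomycin replicate 2. Mb, the myoglobin gene, had 8.68 CPM in control replicate 1 and at most 0.544 CPM elsewhere, and Nppb had 3 control counts, with a ratio of 6.67 and a 95% counting interval from 2.27 to 38.8. Of 11 immediate early genes, 2 rose, with the same number adjusted over the list alone, and the list did not pass (median 0.05, camera adjusted p = 0.409). The immediate early median was 0.551 without control replicate 1 and -0.162 without bleomycin replicate 2. Atf3 rose 2.55-fold and Junb 1.70-fold; 3 immediate early genes rose and 3 fell without bleomycin replicate 2, and 2 rose and 1 fell without bleomycin replicate 1. Of 4 Y-linked genes 1 rose, Eif2s3y by 0.55 ± 0.10 on the log2 scale, also adjusted over the list alone, Ddx3y had a log2 change of 0.47 ± 0.69, and the list did not pass (camera adjusted p = 0.579). Kdm5d, chosen after its values were seen, had between 60.2 and 66.5 CPM in all 4 libraries, while Ddx3y had only 0.275 to 0.749 CPM.

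**Figure D3:**
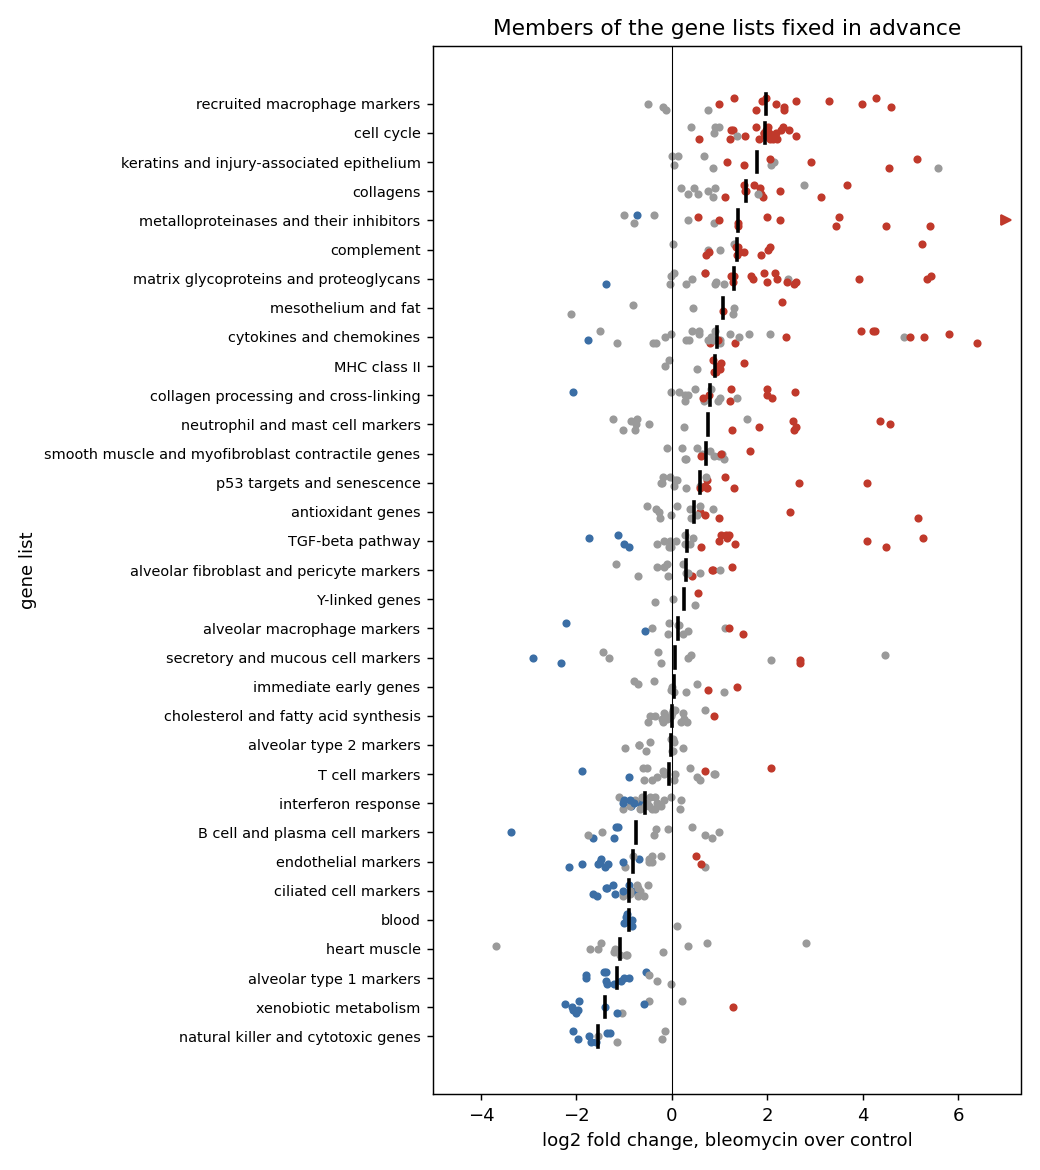
Each point is a tested member of a gene list fixed in advance, placed by its log2 fold change of bleomycin over control, in red where called higher, blue where called lower and grey where not called by edgeR, and the black bar is the list's median. Lists are ordered by median, from -1.54 for natural killer and cytotoxic genes to 1.97 for recruited macrophage markers; the arrowhead is Mmp7, whose fitted value lies beyond the axis.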

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

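The member counts of the lists with a library left out were chosen after the data were seen; the rest was set before. Both counts of called genes stayed within 1.5 times of 1455 and 1223 under every setting that used all 4 libraries, apart from a 2-fold threshold, which by its construction left 880 and 622. Across those settings the higher genes numbered from 1133 (limma-voom) to 2053 (DESeq2) and the lower genes from 1087 (limma-voom) to 1800 (DESeq2). Leaving out each library gave 9 to 2750 higher and 6 to 2612 lower genes. The lone library of a group is then assumed to vary like the other group's pair. With either bleomycin library left out that spread comes from the same control pair, so the number of calls depends on which bleomycin library remains. Bleomycin replicate 1 lay farther from the control mean than replicate 2 for 2150 of the 2678 called genes (80.3%). Every one of the 2678 called genes that was tested kept its direction in every setting. For all of them both bleomycin libraries already lay on the same side of both controls, which left little room for another direction. The kept directions are therefore no separate support for the calls.

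Camera called 23 to 26 lists when each library was left out and 24 with other scaling. It called 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.411. Fry called 0, where 14 lists had one and the smallest adjusted p was 0.0816. For the cytokine list the estimated correlation was 0.00512, below the preset 0.01, yet the unadjusted camera p went from 4.07e-06 to 0.039. For the p53 list it was -0.0268, and that p went from 0.000652 to 0.0663. In these lists a higher correlation among members is therefore not what undid the call. With an estimated correlation camera also takes its p from 2 residual degrees of freedom instead of from the number of genes. That raises p at the same statistic. How much this added in lists with a high estimated correlation was not separated. Directions of lists that did not pass were less stable. By fry the secretory and T cell lists pointed upward, both with an adjusted p of 0.989. Leaving out each library, adjusted p ran from 0.0171 to 0.993 for the secretory list, 0.415 to 0.884 for T cells, 0.195 to 0.792 for cholesterol and fatty acid synthesis, 3.89e-11 to 0.926 for heart muscle and 0.0268 to 0.976 for immediate early genes, with both directions in each. The cause was not tested.

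Of the 98 named genes that were called, 84 stayed past the threshold in every setting with 4 libraries. All 98 kept their sign in every setting, which groups that do not overlap made nearly certain beforehand. The 14 others lost the call in at least 1 such setting. Of the named genes without a call, Ddx3y and Mb changed sign, leaving out each library, from -0.35 (without bleomycin replicate 2) to 0.95 (without bleomycin replicate 1) for the log2 change of Ddx3y, and from -5.72 (without bleomycin replicate 2) to 1.19 (without control replicate 1) for the log2 change of Mb. Without control replicate 1, 93 of the called named genes were not called, and without control replicate 2 also 93; it was 10 without bleomycin replicate 1 and 3 without replicate 2.

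Replicate numbers are shared between the groups, and the labels do not say that they pair the rats; the correlation over genes of the difference between replicates 1 and 2 was -0.00237 between the groups. With a replicate block edgeR called 1331 higher and 1100 lower genes and camera 24 lists; 9 named genes lost their call and 3 gained one. Under the block the directions of 3 lists that did not pass were opposite, with adjusted p of 0.0748 for secretory cells, 0.985 for cholesterol and fatty acid synthesis and 0.915 for heart muscle.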

Other observations

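The gene lists of the next 2 paragraphs, and all tests below except that of transcript length, were chosen after the values were seen, so their p-values are not independent evidence. Lists of endothelial subtypes and a list of caveolar genes, which stands for no cell type, moved in both directions. The arterial list shares Sox17 with the general endothelial list. Of 12 arterial and Notch genes, 5 fell and 1 rose (median log2 change -0.45, camera adjusted p = 0.00626; adjusted p = 0.411 with an estimated correlation). The Notch ligand gene Dll4 fell by 2.19 ± 0.35 and the arterial ephrin gene Efnb2 by 1.70 ± 0.28 on the log2 scale. Of 9 caveolar genes, 6 fell (median -0.86, camera adjusted p = 0.000406; adjusted p = 0.411 with an estimated correlation), with Cav1, caveolin 1, at 1766 and 1544 CPM in the controls against 519.7 and 718.3 CPM after bleomycin. Of 7 activated and systemic venous genes, 5 rose (median 1.12, camera adjusted p = 0.00068; adjusted p = 0.403 with an estimated correlation), among them the adhesion molecule genes Sele, by 2.37 ± 0.32, and Vcam1, by 1.27 ± 0.14. Of 7 lymphatic genes, 3 rose and 1 fell, and the list did not pass (camera adjusted p = 0.21, or 0.037 without bleomycin replicate 2): Prox1, the lymphatic transcription factor gene, rose by 1.17 ± 0.25, while Lyve1, which macrophages also express, fell by 2.12 ± 0.14.

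Genes of rare airway cell types and of cell metabolism also differed. Of 22 tuft cell markers, 8 fell and 2 rose (median -0.93, camera adjusted p = 0.00068; adjusted p = 0.411 with an estimated correlation). The ion channel gene Trpm5 fell by 3.21 ± 0.28 and the transcription factor gene Pou2f3 by 2.53 ± 0.53, while Hpgds and Ptgs1, prostaglandin enzymes that other cells also express, rose by 1.61 ± 0.23 and 0.98 ± 0.21. Of 16 neuroendocrine genes, 5 rose (median 1.01, camera adjusted p = 0.00476; adjusted p = 0.403 with an estimated correlation), with the secretory granule gene Ptprn at 26.7 and 12.8 CPM after bleomycin against 0.550 and 0.298 CPM in the controls. Of 20 endoplasmic reticulum chaperone genes, 12 rose (median 0.58, camera adjusted p = 2.45e-05; adjusted p = 0.411 with an estimated correlation), and of 21 glycolysis genes 9 rose (median 0.71, camera adjusted p = 6.66e-05; adjusted p = 0.411 with an estimated correlation), among them Hk2 by 1.48 ± 0.15 and Slc16a3, a lactate transporter gene, by 1.89 ± 0.36. Of 25 genes of serine, one-carbon and amino acid supply, 6 rose and 1 fell (median 0.44, camera adjusted p = 0.0041; adjusted p = 0.411 with an estimated correlation), with the mitochondrial folate enzyme gene Aldh1l2 at 21.6 and 3.70 CPM after bleomycin against 0.0579 and 0.138 CPM. With an estimated correlation none of these 9 lists passed, with camera adjusted p from 0.403 to 0.531, and fry called 2 of them, the venous and neuroendocrine lists (adjusted p = 0.00689 for both). All of these lists except the lymphatic list kept their side of the threshold when each library was left out.

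The bleomycin libraries stood farther apart than the controls, and a candidate explanation is a smaller response along the same axis in replicate 2, whether a weaker response or more unaffected tissue in the piece. Across the 15709 tested genes the difference between the bleomycin libraries correlated with their mean effect (Pearson's r = 0.408), which as the test first run would have counted for it. That mean contains replicate 1 itself, so after its value was seen it was replaced by the effect in replicate 2 alone; r was then 0.0855, which noise in replicate 2 pulls below 0, and the explanation could not be told apart from its absence. The difference correlated weakly with transcript length (Spearman's rho = -0.1, against 0.0545 for the control pair), at the bound set in advance below which length would have been ruled out, so a part from RNA quality cannot be told apart either.

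Of the alveolar type 1 and endothelial markers 11 of 14 and 9 of 19 were called lower, and of the type 2 markers 0 of 11. Dilution of all resident cells alike by incoming cells would lower the type 1 and type 2 lists equally, but their medians differed by -1.12 (two-sided permutation p = 0.00058 with 1e+05 resamples of genes). Because genes of a list are correlated, which that p leaves out, the difference of medians was also taken per library. An exact permutation test of 2 against 2 cannot go below p = 0.333. Each library was set against the control mean, so the controls mirror each other around 0 and only their distance apart is informative. The type 1 difference was -1.19 and -1.06 in bleomycin replicates 1 and 2, against -0.019 and 0.019 in the controls. For endothelial against type 2 markers it was -0.774 and -0.852, against 0.0962 and -0.0962. The type 1 difference lay outside the range of the 2 libraries within each group, which argues against dilution as the whole cause. A rise of type 2 cells on top of dilution was not excluded. The type 2 median itself was 0.212 without bleomycin replicate 1 and -0.339 without replicate 2. Type 2 members were uneven, with log2 changes from -0.99 to 0.24. List means lay closer together than the medians, at -1.05 for type 1 and -0.28 for type 2 markers. That 78.6% of the type 1 markers were called lower restates the fall and is no test of its cause, and fewer type 1 cells cannot be told apart from lower expression per cell in whole tissue.

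Of the natural killer genes 7 of 11, of the haemoglobin and erythroid genes 5 of 6 and of the B cell markers 5 of 14 were called lower, and none of these lists passed with an estimated correlation (adjusted p = 0.427 for each). A lower share of all lymphocytes would lower natural killer and T cell lists alike, and their medians differed by -1.48 (two-sided permutation p = 0.00054 over genes). Per library the difference was -2.35 and -0.859 in bleomycin replicates 1 and 2, a range of 1.49 that exceeds the size of their mean, -1.61, less a tolerance of 0.3, so a lower share of all lymphocytes cannot be told apart from a change of natural killer cells. Less blood in the treated pieces could lower both circulating cells and haemoglobin. The comparison of natural killer with blood genes was made the test of this after both differences had been seen. The natural killer median lay -0.644 from that of the 6 blood genes (permutation p = 0.066). Per library the difference was -1.08 and -0.356 in bleomycin replicates 1 and 2. The controls were at -0.368 and 0.368, mirrored around 0 by the same centring. Less blood therefore cannot be told apart from fewer natural killer cells.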
